A study of Mus musculus with 10 samples.

How the data were processed

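RNA was measured in the pooled gastrocnemius and plantaris, calf muscles of the hindlimb, of 10 male C57BL/6 mice aged 12 weeks. After a fast of about 16 h, 5 mice received an intraperitoneal injection of saline and 5 received ethanol at 3 g/kg, a single binge-like dose. Muscle was taken 1 h later. Per the labels' protocols, polyadenylated RNA was made into libraries that were sequenced from a single end. The groups are named saline (mice 32, 34, 36, 38 and 39) and ethanol (mice 51, 57, 59, 60 and 62), after the animal numbers in the labels. The animal numbers of the groups do not overlap, and the labels name no batch, litter, pairing or time of day of tissue collection, so no block entered the fit.

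The authors deposited 1 table of whole-number read counts per gene symbol, with a column for each library. Per the submitters' processing notes, TopHat2, DESeq2 1.6.3 and the mm10 build were used, with no role given for each. The read counter, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies, could be assigned in ways that cannot be checked. The table has 24421 rows. In 27 rows the symbol had been replaced by a calendar date, as spreadsheet software does to some gene names, and these rows were kept in the totals as unnamed features. Mitochondrially encoded genes and the share of counts they take were not analysed here.

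Counts were analysed as deposited. Genes were kept by edgeR's filterByExpr at its default minimum count of 10 and minimum total count of 15, which left 13180 genes. Libraries were scaled by TMM. The main test was the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion estimates, ethanol minus saline, with Benjamini-Hochberg adjustment and a false discovery rate (FDR) threshold of 0.05. Standard errors are the log2 fold change divided by the square root of its F statistic, and intervals are 95% intervals. Levels are TMM-scaled CPM (counts scaled to a fixed library total), and log2 CPM values carry a prior count of 2. Gene coordinates and transcript GC content come from GENCODE M21 on GRCm38, which may differ from the annotation the authors used. A GC content was found for 12709 of the tested genes (96.4%).

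The design, the alternatives, the rule for named genes and 38 gene lists were fixed before the data were examined. Of the lists, 36 had at least 3 tested members, and the mitochondrially encoded and lymphocyte lists had 0. Each was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, a rotation test, both directional and mixed. Each family was adjusted over the 36 lists. List means per library (mean log2 CPM) and library measures were compared by two-sided exact permutation over the 252 labelled splits of the 10 libraries, which cannot give a p below 0.00794. Principal components used the 500 most variable genes.

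Named genes were to be the largest changes among genes that passed the FDR threshold, at a mean of at least 2 CPM and with groups that did not overlap. No gene qualified for that part. The rule also named every tested core clock gene, of which 1 is counted in the list but not reported here, and, from each other list, up to 4 members with the smallest p. Of these, the text names members of lists that passed camera, members that passed when adjusted over their list alone, and a few members of other lists that bear on the treatment, a choice made after the values were seen. Genes outside the rule are said to be so where they appear.

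The alternatives fixed in advance were DESeq2 1.42.0 at its default settings, limma-voom, median-of-ratios (RLE) size factors, scaling by total count alone, no low-count filter, a mean of at least 5 CPM, 1 surrogate variable from sva 3.50.0, dispersion without robust estimation, and leaving out each library in turn. After the data were seen, fits were added without saline 36 and ethanol 60, with the GC trend of each library removed by lowess (span 0.3), with all libraries thinned to the smallest total, with the adipocyte list mean as a covariate, and with DESeq2's independent filtering set for 0.05. All ran in R 4.3.3.

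The procedure was tested on simulated counts drawn for the 13180 genes of the ethanol and saline comparison from the real means and library sizes, with 200 genes changed per run. It recovered 54.6% of genes changed 1.5-fold, 86.0% of those changed 2-fold and 95.5% of those changed 3-fold. False calls made up 5.07% of calls, and runs without any changed gene gave at most 2 calls. The simulated genes varied independently of each other, with no shifts shared by the genes of a library and no outlying mice. These rates may therefore not hold for the real libraries, where genes vary together. Within-group pairs of libraries differed by far more than sampling noise, with a chi-square per degree of freedom between 13.1 and 92.8 over genes with a joint count of at least 10, so no library was treated as a duplicate.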

Results

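Poly(A) RNA of mouse calf muscle was counted per gene in 10 libraries, 5 from saline-injected and 5 from ethanol-injected mice, 1 h after the injection. Library totals ran from 32.0 to 42.7 M counts in the saline group and from 20.3 to 31.3 M in the ethanol group. The mean total was 37.4 ± 4.12 M in saline and 26.8 ± 4.02 M in ethanol (SD, n = 5 each, two-sided exact permutation p = 0.00794, adjusted p = 0.0238), so every ethanol library was shallower than every saline library. The 10 most counted genes took 20.5 ± 0.65% of counts in saline and 21.6 ± 0.64% in ethanol (SD, n = 5 each, exact permutation p = 0.0397, adjusted p = 0.0397). Fewer genes had a count in the ethanol libraries (16010 ± 188 against 16280 ± 113, SD, n = 5 each, exact permutation p = 0.0397, adjusted p = 0.0397). After all libraries were thinned to the smallest total the means were 15770 and 15710 (exact permutation p = 0.341). The slope of centred log2 CPM on transcript GC content was -0.044 ± 0.038 per 10% GC in saline and 0.044 ± 0.015 in ethanol (SD, n = 5 each, exact permutation p = 0.00794), so GC-rich transcripts ran higher in the ethanol libraries. Each gene was centred on its mean over the 10 libraries. This makes the group means equal and opposite by construction, so only their difference is measured.

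Log2 CPM correlated between libraries at 0.983 to 0.993 within groups and at 0.978 to 0.994 between groups. The first principal component held 32.0% of the variance of the 500 most variable genes, and the second 20.1%. Saline 36 lay at one end of the first component, at -20.5, with the other saline libraries between -6.48 and 2.85 and the ethanol libraries between -1.36 and 12.4. The group means on it were -5.69 ± 8.95 in saline and 5.69 ± 5.60 in ethanol (SD, n = 5 each, exact permutation p = 0.0317, not a planned test). Genes with the largest loadings toward saline 36 included *Slc39a14*, *Sesn1* and *Musk*. Ethanol 60 lay alone at -17.1 on the second component, toward the adipocyte genes *Lep*, *Retn*, *Pck1* and *Plin1*. *Lep* and *Retn* are outside the rule for named genes.

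**Figure D1:**
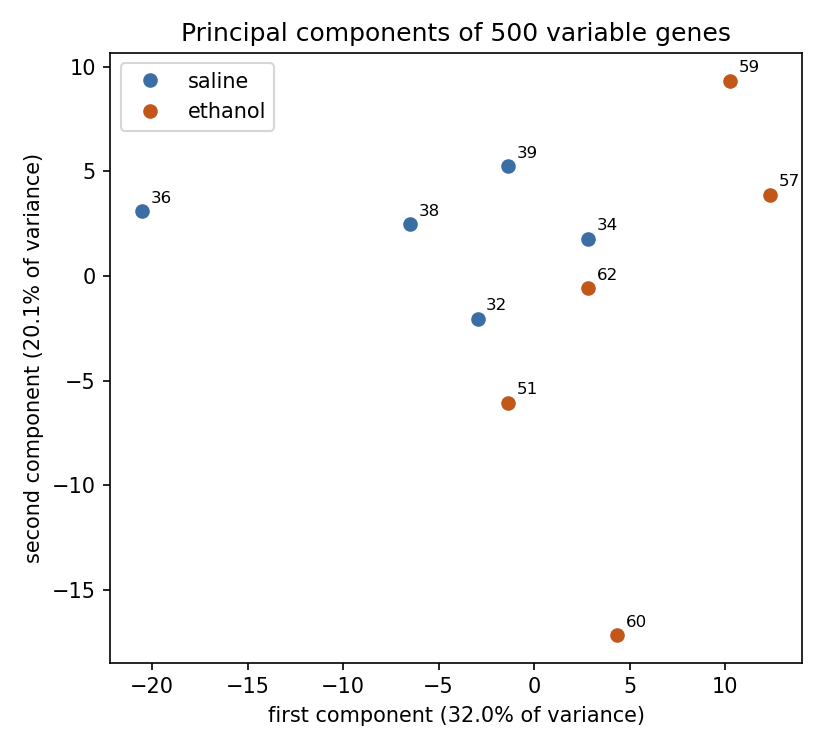
Position of each library on the first and second principal components of log2 CPM, in arbitrary units, for saline (blue) and ethanol (orange) libraries labelled by animal number. Saline 36 lies at -20.5 on the first component and ethanol 60 at -17.1 on the second. The other saline libraries lie between -6.48 and 2.85 on the first component, and the ethanol libraries between -1.36 and 12.4.

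The main comparison asked which muscle transcripts differed 1 h after ethanol. Effects were small: 60 of 13180 genes had a log2 fold change beyond 1 in either direction, and the median half-width of the 95% interval was 0.25 log2 units. By edgeR's quasi-likelihood test 0 genes passed FDR 0.05, and the smallest FDR was 0.214. At an unadjusted p under 0.05 there were 1599 genes, 820 higher and 779 lower in ethanol, against 659 expected by chance. With 1 surrogate variable there were 952, and with the adipocyte mean as a covariate 918. The groups did not overlap in CPM for 287 genes, 2.18% of those tested, where chance gives 0.794% on average. Genes vary together between libraries, so such counts can spread widely around the averages that chance gives. Of 100 splits of the libraries, the real one included, 6 gave at least 1599 genes at an unadjusted p under 0.05. The 287 genes were not set against other splits. DESeq2 called 54 genes, 38 higher and 16 lower, and limma-voom called 0.

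The 8 genes of this paragraph were singled out, from those with small p, after their values were seen. *Rgcc*, a regulator of the cell cycle, stood at 131 ± 16.4 CPM in saline and 84.2 ± 11.2 CPM in ethanol (SD, n = 5 each), a log2 fold change of -0.64 ± 0.11 (SE, edgeR FDR = 0.214, lower in 5 of 5 ethanol libraries). *Lmod2*, which elongates the thin filaments of the sarcomere, stood at 640 ± 112 and 433 ± 15.3 CPM (log2 fold change -0.56 ± 0.11), and *Xirp1*, an actin-binding protein of the muscle attachment sites, at 566 ± 145 and 345 ± 51.7 CPM (-0.71 ± 0.16). Saline 38 and saline 39 held 743 and 703 CPM of *Xirp1*, against 434 to 487 in the other saline and 301 to 428 in the ethanol libraries. *Plxnd1*, a semaphorin receptor of endothelium, stood at 29.8 ± 2.43 and 39.2 ± 1.90 CPM (0.39 ± 0.07). *Emilin1*, an elastic fibre glycoprotein (0.56 ± 0.11), the secreted protein gene *C1qtnf1* (0.57 ± 0.11) and the stromal cell marker *Cd248* (0.74 ± 0.15) were also at higher counts, and the zinc finger gene *Zfp655* at lower ones (-0.53 ± 0.10). These 8 genes were among the 54 that DESeq2 called, *Rgcc* at an adjusted p of 5.98e-04. Of the edgeR fits with a library left out, *Rgcc* passed in the one without saline 34 (FDR = 0.0497). That fit leaves out the saline library nearest to the ethanol group, with 102.8 CPM of *Rgcc* against 132 to 143 in the other saline libraries.

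The series title names the molecular clock of muscle as its subject. None of the 18 core clock genes passed FDR 0.05, with edgeR or with DESeq2, and 0 passed when adjusted over the list alone (smallest adjusted p 0.0748). Log2 fold changes were positive for 5 and negative for 13 genes, with 4 at an unadjusted p under 0.05 in edgeR. The repressor gene *Cry1* (GRCm38 chromosome 10, 85131700 to 85185064) stood at 14.7 ± 1.75 CPM in saline and 11.2 ± 2.30 in ethanol (SD, n = 5 each). Its log2 fold change was -0.39 ± 0.13 (SE, FDR = 0.322). *Per3*, a period gene (chromosome 4, 151003652 to 151044665), stood at 3.09 ± 0.50 and 4.81 ± 1.68 CPM, a log2 fold change of 0.64 ± 0.21 (FDR = 0.322). *Bhlhe41*, also called DEC2, a transcriptional repressor (chromosome 6, 145858243 to 145865558), stood at 19.3 ± 4.22 and 33.7 ± 13.7 CPM (0.80 ± 0.26, FDR = 0.332). Ethanol 57 and ethanol 59 held the highest values of both, 40.3 and 54.7 CPM of *Bhlhe41* and 6.07 and 7.04 of *Per3*, against 23.1 to 26.5 and 3.01 to 4.21 in the other ethanol libraries, where the highest saline library held 24.0 and 3.59. *Clock* itself (chromosome 5, 76209868 to 76304792) stood at 48.5 ± 6.83 and 41.7 ± 2.86 CPM (-0.22 ± 0.09, FDR = 0.393).

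The partner of CLOCK, *Arntl* (BMAL1, chromosome 7, 113207465 to 113314126), was at 70.0 ± 22.2 CPM in saline and 55.6 ± 18.1 in ethanol (SD, n = 5 each), with a log2 fold change of -0.33 and a 95% interval from -0.93 to 0.26. The interval also included 0 for *Npas2* (-0.21), *Per1* (-0.27), *Per2* (-0.13), *Cry2* (-0.60), *Rora* (-0.48), *Csnk1e* (-0.13), *Csnk1d* (-0.06), *Nr1d1* (0.23), *Nr1d2* (-0.06), *Timeless* (0.04), *Ciart* (0.02) and *Bhlhe40* (-0.0037). The signs of *Csnk1d*, *Nr1d2*, *Timeless*, *Ciart* and *Bhlhe40* depended on the processing. Saline 36 held the highest CPM of *Cry2*, *Arntl*, *Rora*, *Npas2*, *Per1* and *Csnk1e* (239 CPM of *Cry2* against 65.1 to 113 in the other saline libraries), and without it their log2 fold changes were -0.215, -0.136, -0.242, -0.011, -0.147 and -0.020. Other single libraries moved *Arntl* (-0.50 without ethanol 51, -0.20 without ethanol 57), *Npas2* (-0.35 without saline 39, -0.07 without ethanol 57), *Per1* (-0.177 without ethanol 62), *Per2* (-0.22 without ethanol 59, -0.214 without ethanol 57, -0.206 without saline 32, -0.05 without saline 38, -0.02 without ethanol 62) and *Nr1d1* (0.116 without ethanol 59, 0.145 without saline 34). As a list the core clock did not pass camera (median log2 fold change -0.13, adjusted p = 0.178). The 14 clock output genes, which the clock drives, split into 7 positive and 7 negative fold changes (camera adjusted p = 0.868). Among them *Dbp* was at 0.53 ± 0.24 (log2 fold change ± SE, 0.30 without ethanol 57) and *Nfil3* at -0.72 ± 0.34 (-0.37 without saline 36). Ethanol 57 and ethanol 59 also held the highest CPM of *Dbp*, 15.2 and 12.7, against 6.10 to 7.33 in the other ethanol libraries.

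**Figure D2:**
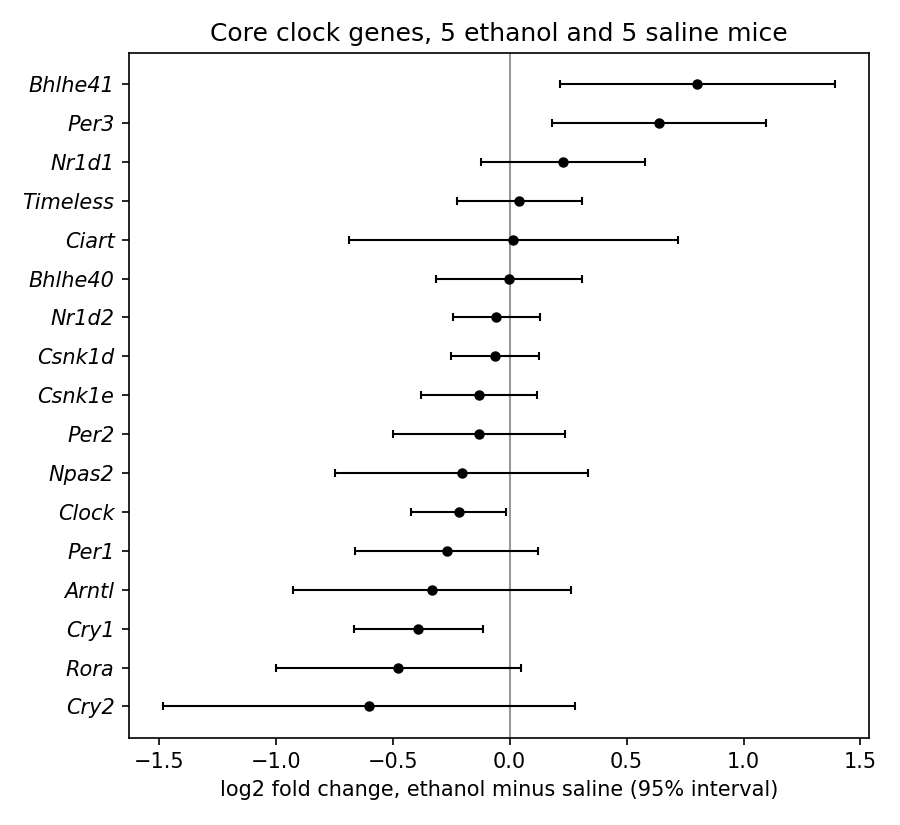
Log2 fold change, ethanol minus saline, of 17 of the 18 core clock genes (points) with the 95% interval (bars), from 5 libraries per group. The intervals of Bhlhe41, Per3, Clock and Cry1 exclude 0, with values of 0.80, 0.64, -0.22 and -0.39, and none passed FDR 0.05.

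Glucocorticoids are the other subject of the title. Of the 20 tested glucocorticoid receptor target genes, none passed FDR 0.05 over all genes with edgeR or DESeq2, and 0 passed when adjusted over the list alone (smallest adjusted p 0.167), but all 20 had a negative log2 fold change, with a median of -0.53. Camera placed the list lower in ethanol (adjusted p = 2.69e-06 with the preset correlation, adjusted p = 0.521 with an estimated correlation). The genes moved closely together from library to library, with an estimated correlation of 0.69. The list mean was 7.29 ± 0.53 log2 CPM in saline and 6.76 ± 0.38 in ethanol (SD, n = 5 each, exact permutation p = 0.111). Saline 36 held the highest mean, 8.16, and without it the median log2 fold change was -0.25, or -0.35 without ethanol 60 as well. *Tsc22d3*, encoding the glucocorticoid-induced leucine zipper protein, was at 459 ± 165 and 334 ± 33.8 CPM (log2 fold change -0.46 ± 0.19, SE, FDR = 0.393). Saline 36 held 739 CPM of it, against 334 to 453 in the other saline libraries, and without it the log2 fold change was -0.228. The zinc transporter gene *Slc39a14* (-1.50 ± 0.63), the metallothionein gene *Mt1* (-0.87 ± 0.37) and the kinase gene *Map3k6* (-0.75 ± 0.35) had larger values and larger errors, and saline 36 held 278 CPM of *Slc39a14* against 28.2 to 93.9 in the other saline libraries. Without it the values were -0.59, -0.57 and -0.42.

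Several lists of muscle stress and protein turnover were placed lower by camera, and none of them kept its call with an estimated correlation. Among 22 autophagy genes 20 had negative fold changes (median -0.14, adjusted p = 2.58e-04, adjusted p = 0.521 with an estimated correlation). Its members included the lysosomal membrane gene *Lamp2* (-0.28 ± 0.09, log2 ± SE), the autophagosome genes *Map1lc3b* (-0.32 ± 0.12) and *Gabarapl1* (-0.51 ± 0.19), and the mitophagy receptor gene *Bnip3* (-0.49 ± 0.18). Among 20 heat shock genes 16 were negative (adjusted p = 0.00245, adjusted p = 0.534 with an estimated correlation, adjusted p = 0.0766 without saline 39). *Hspb7*, a small heat shock protein gene of muscle, was at 1154 ± 116 CPM in saline and 920 ± 92.5 in ethanol, and *Hspb1* was at 568 ± 123 and 409 ± 66.2 (SD, n = 5 each). Saline 38 and saline 39 held 688 and 715 CPM of *Hspb1*, against 457 to 497 in the other saline and 342 to 494 in the ethanol libraries. The chaperone genes *Dnajb1* and *Hspa1a* were at -0.82 ± 0.31 and -0.73 ± 0.31 (log2 ± SE, FDR = 0.364 and 0.395), with the highest values in saline 38 and saline 39: 31.0 and 20.7 CPM of *Dnajb1*, against 9.82 to 13.1 in the other saline and 8.56 to 10.99 in the ethanol libraries. Without saline 38 the values were -0.49 for *Dnajb1* and -0.39 for *Hspa1a*. The heat shock list mean was 7.27 log2 CPM in saline 38 and 7.29 in saline 39, 6.78 to 6.85 in the other saline libraries and 6.71 to 6.92 in ethanol. Of 20 ubiquitin ligase and atrophy genes 15 were negative (adjusted p = 0.0464, adjusted p = 0.551 with an estimated correlation). This call was lost without saline 36, saline 38, ethanol 57, ethanol 59 or ethanol 62, at an adjusted p of 0.133, 0.0909, 0.157, 0.1001 and 0.0644, and with genes at 5 CPM or more (adjusted p = 0.114), after thinning (adjusted p = 0.0538) and with the adipocyte mean as a covariate (adjusted p = 0.0864). *Fbxo30*, a ubiquitin ligase subunit gene, was at -0.57 ± 0.23, the F-box gene *Fbxo21* at 0.38 ± 0.12 and *Mstn*, encoding the muscle growth inhibitor myostatin, at -0.82 ± 0.32. Saline 36 held 204 CPM of *Mstn*, against 73.8 to 152 in the other saline libraries. Saline 36 also held the highest mean of the autophagy list, 6.88 log2 CPM.

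All 29 tested ribosomal protein genes had slightly negative fold changes (median -0.10, camera adjusted p = 0.00245, adjusted p = 0.730 with an estimated correlation), with *Rpl5* at -0.20 ± 0.10 and *Rpl32* at -0.19 ± 0.11 (log2 ± SE; *Rpl32* -0.12 without saline 34). That call was lost without saline 34 (adjusted p = 0.167) or ethanol 60 (adjusted p = 0.0956) and with the adipocyte mean as a covariate (adjusted p = 0.608), and with 1 surrogate variable camera placed the list higher (adjusted p = 0.884). Immediate early genes, which respond within minutes to hormones and contraction, did not pass as a list (camera adjusted p = 0.118), but were placed lower with total count scaling (adjusted p = 0.0478), 1 surrogate variable (adjusted p = 0.00356), without saline 32 (adjusted p = 0.00656) or saline 34 (adjusted p = 0.0163) and with the GC trend removed (adjusted p = 0.0386). Among them *Fos* stood at 144 ± 105 CPM in saline (307 in saline 38 and 188 in saline 39) and 53.3 ± 16.8 in ethanol (SD, n = 5 each), *Atf3* at 50.3 ± 28.4 and 19.1 ± 6.18, *Maff* at 66.5 ± 36.4 and 30.1 ± 8.53, and *Klf6* at 103 ± 15.04 and 81.4 ± 5.05. Their edgeR FDR values were 0.341, 0.287, 0.322 and 0.287. The log2 fold change of *Fos* was -1.43, or -0.95 without saline 38, and that of *Maff* -1.14, or -0.75 without saline 36. Saline 38 also held 96.9 CPM of *Atf3*, against 26.7 to 54.6 in the other saline libraries.

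Camera placed the adipocyte, fibroblast, endothelial, satellite cell and interferon-stimulated lists higher and the neutrophil list lower, and the macrophage, pericyte and tendon lists did not pass. None of the lists so placed kept its call with an estimated correlation. Macrophage genes were placed higher with no low-count filter, without saline 38 and without ethanol 59 (adjusted p = 0.0373, 0.0197 and 0.00153), and tendon genes with total count scaling, no low-count filter, 1 surrogate variable, without saline 32, saline 36, ethanol 59 or saline 36 and ethanol 60 together (adjusted p from 0.00249 to 0.0478). Of 11 adipocyte genes 10 had positive fold changes (median 0.83, adjusted p = 2.66e-04, adjusted p = 0.521 with an estimated correlation), and 1 of them passed when adjusted over the list alone. This was *Lipe*, encoding hormone-sensitive lipase, at 34.2 ± 2.66 CPM in saline and 49.8 ± 12.0 in ethanol (SD, n = 5 each), which DESeq2 also called (adjusted p = 0.0493), but not with its independent filtering set for 0.05. *Pck1*, an enzyme gene of glyceroneogenesis, was at 19.98 ± 6.25 and 58.0 ± 48.9 CPM and the lipid droplet gene *Plin1* at 6.00 ± 1.35 and 14.3 ± 10.4. Ethanol 60 held 144 CPM of *Pck1*, against 29.0 to 52.5 in the other ethanol libraries. Without it the log2 fold change of *Pck1* went from 1.53 to 0.87 and that of *Plin1* from 1.24 to 0.72, and the median of the list was 0.35, or 0.22 without saline 36 as well. With 1 surrogate variable the median was 0.15 and the adipocyte call was lost (adjusted p = 0.487). Of 14 fibroblast and fibro-adipogenic progenitor (FAP) genes 13 were positive (median 0.16, adjusted p = 2.66e-04, adjusted p = 0.521 with an estimated correlation), and 3 passed when adjusted over the list alone: *Pi16* (0.48 ± 0.13), the collagen genes *Col6a1* (0.45 ± 0.12) and *Col3a1* (0.46 ± 0.14). With the adipocyte mean as a covariate the fibroblast list had an adjusted p of 0.161. That covariate itself ran with the groups, at 4.70 log2 CPM in saline and 5.35 in ethanol (exact permutation p = 0.0397, adjusted p = 0.405). It can therefore take up part of the ethanol contrast. A call lost with it, for this or another list, does not show that fat accounts for the call.

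Of 14 endothelial genes 11 were positive (adjusted p = 0.0464, adjusted p = 0.551 with an estimated correlation), among them the receptor genes *Kdr* (0.46 ± 0.14, log2 ± SE) and *Tie1* (0.20 ± 0.07). The endothelial call was lost when any of saline 32, saline 34, saline 38, saline 39, ethanol 51, ethanol 60 or ethanol 62 was left out, at adjusted p values from 0.0622 to 0.206, and with 1 surrogate variable (adjusted p = 0.347), the GC trend removed (adjusted p = 0.0860) or the adipocyte covariate (adjusted p = 0.183). Of 20 interferon-stimulated genes 19 were positive (adjusted p = 0.00609, adjusted p = 0.551 with an estimated correlation), with *Gbp2* at 0.38 ± 0.17 and *Bst2* at 0.35 ± 0.17. Over the alternatives *Gbp2* ran from 0.06 to 0.45 and *Bst2* from 0.14 to 0.52. The interferon-stimulated call was lost without saline 39 (adjusted p = 0.0514) or ethanol 57 (adjusted p = 0.157), without saline 36 and ethanol 60 together (adjusted p = 0.0861) and with the adipocyte covariate (adjusted p = 0.448). Of 13 satellite cell and myogenic genes 10 were positive (adjusted p = 0.0261, adjusted p = 0.521 with an estimated correlation). All ethanol libraries lay above all saline libraries in the mean of this list, 3.35 ± 0.05 against 3.17 ± 0.08 log2 CPM (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.286). The gap was narrow, with saline 39 at 3.276 and ethanol 57 at 3.282. *Pax7*, the transcription factor gene of satellite cells, was at 0.86 ± 0.15 and 1.59 ± 0.35 CPM and was the 1 member that passed when adjusted over the list alone. DESeq2 called it (adjusted p = 0.0322). *Myod1*, a regulator of myogenic differentiation, was at 4.37 ± 1.06 and 8.23 ± 4.14 CPM, with 12.0 and 13.4 CPM in ethanol 57 and ethanol 59, 4.84 to 5.91 in the other ethanol libraries and 3.07 to 5.47 in saline. The list was lost without saline 32, saline 34 or ethanol 51, at an adjusted p of 0.0515, 0.0827 and 0.0548, without saline 36 and ethanol 60 together (0.0861), with 1 surrogate variable (0.2004) and with the adipocyte covariate (0.1395).

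Of 6 tested neutrophil genes 5 were negative (median -1.18, adjusted p = 0.00589, adjusted p = 0.521 with an estimated correlation). *S100a8*, a calprotectin subunit gene, was at 1.39 ± 1.04 CPM in saline and 0.42 ± 0.28 in ethanol (SD, n = 5 each), and passed when adjusted over the list alone. *S100a9* was at 2.48 ± 1.91 and 0.84 ± 0.59 CPM, and *Retnlg* at 0.80 ± 0.67 and 0.22 ± 0.31. Saline 39 held the highest list mean, and without it the adjusted p was 0.0514, the median -0.61 and the log2 fold changes of *S100a9* and *Retnlg* -0.95 and -1.15, against -1.54 and -1.78 with it (*Retnlg* -3.31 without ethanol 57). After thinning to equal depth the adjusted p was 0.0722 and the median -0.61. The low-count filter was applied again after thinning and left 12692 genes. This median may therefore rest on other members than the one without thinning.

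**Figure D3:**
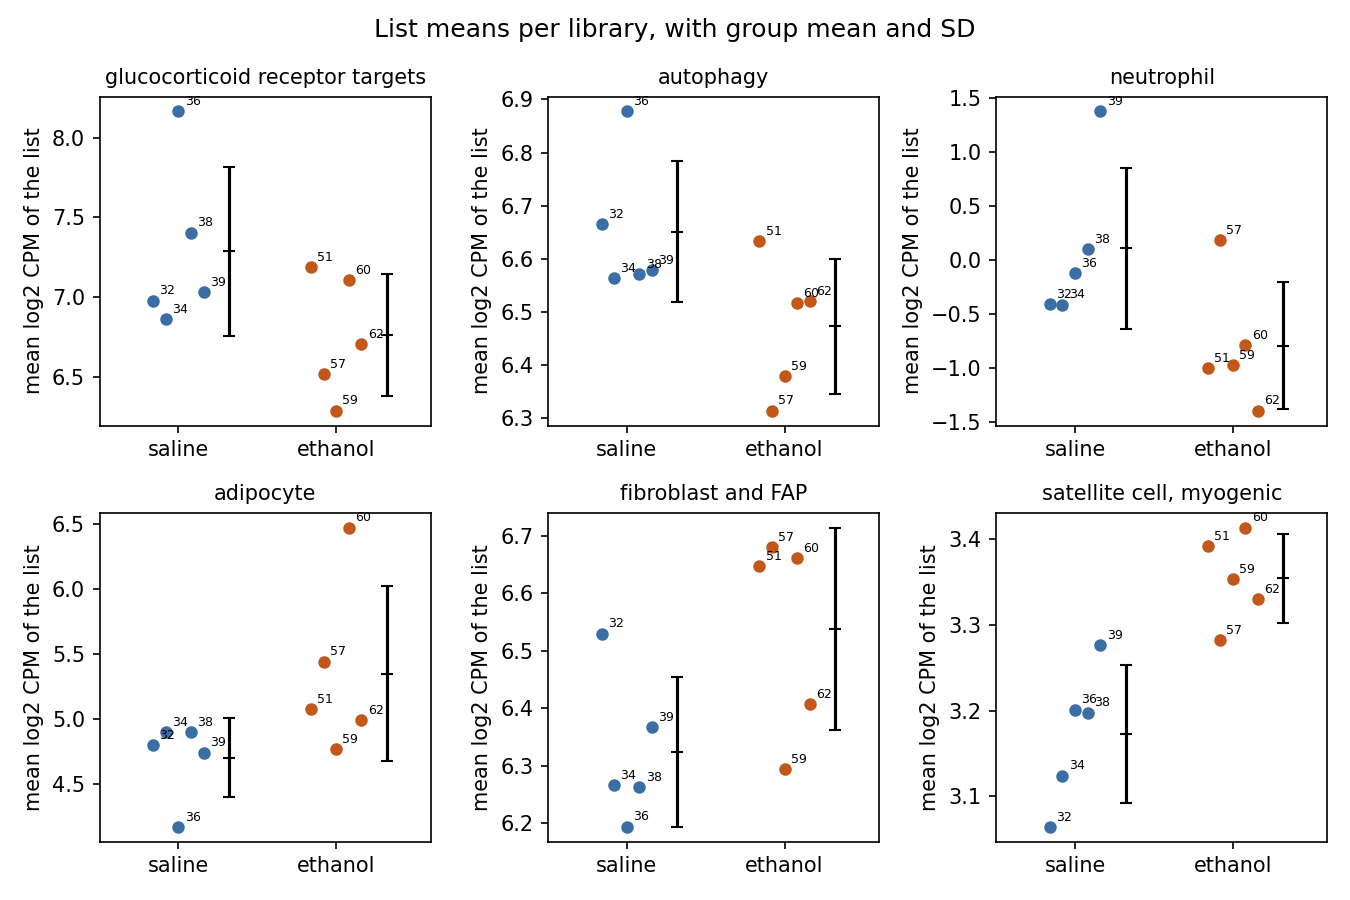
Mean log2 CPM of 6 gene lists in each library (points, labelled by animal number), with the mean and SD of each group of 5 (black). Saline 36 lies highest for glucocorticoid receptor targets, at 8.16, and saline 39 highest for neutrophil genes, at 1.38. The groups separate by a narrow gap for the satellite cell list, with means of 3.17 and 3.35.

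Camera thus called 11 of 36 lists, 6 lower and 5 higher, and 0 with an estimated correlation or with fry's directional test. Fry's mixed test, which asks whether members change in either direction, passed 1 list, satellite cell and myogenic (adjusted p = 0.00560). The other 25 had adjusted p values from 0.0570 (mTORC1 signalling and amino acid transport) to 0.934 (Schwann cell and nerve), and 10 of them passed in at least 1 alternative. The mTORC1 list was placed lower in 6, with total count scaling, no low-count filter, 1 surrogate variable, without saline 34, without ethanol 60 and with the GC trend removed (adjusted p = 0.0478, 0.0232, 0.0295, 0.0149, 0.0478 and 0.0270). The 25 included hypoxia, glycolysis, fatty acid oxidation, the nuclear-encoded respiratory chain, slow and fast fibre genes, p53 targets, the cAMP and PGC-1 response, the integrated stress response, cold-responsive genes, inflammatory cytokines, macrophage, pericyte, tendon and erythroid markers. Single genes in such lists passed when adjusted over their list alone. This adjustment, here and above, does not correct for the number of lists. Over all genes the edgeR FDR of those named next was 0.284 for *Sat1* and 0.287 for *Irs2*, *Igfbp5*, *Sod3* and *Ache*. In insulin and IGF signalling there were 2, *Irs2*, an insulin receptor substrate gene, at 72.7 ± 11.01 and 38.2 ± 12.4 CPM (SD, n = 5 each), and *Igfbp5*, an IGF-binding protein gene, at 112 ± 18.4 and 150 ± 22.8. *Irs2* also passed in the cAMP list, *Sat1*, the polyamine acetyltransferase gene, in the polyamine list (-0.36 ± 0.08, log2 ± SE), *Sod3*, extracellular superoxide dismutase, in the NRF2 list (0.54 ± 0.13) and *Ache*, acetylcholinesterase, in the neuromuscular junction list (0.48 ± 0.12). DESeq2 called *Irs2* (adjusted p = 0.00321), *Sat1* (adjusted p = 0.0203) and *Sod3* (adjusted p = 0.0478) over all genes. *Musk*, encoding the receptor kinase of the neuromuscular junction, was at 63.2 ± 39.9 and 28.1 ± 7.38 CPM. Saline 36 held 120 CPM of it, against 21.2 to 86.4 in the other saline libraries. Of 14 ethanol and aldehyde metabolism genes 0 passed when adjusted over the list alone (camera adjusted p = 0.766). *Acss1*, a mitochondrial acetyl-CoA synthetase gene, was at -0.61 ± 0.26 and the ethanol-oxidising *Cyp2e1* at 0.92 ± 0.47, the latter 0.34 without ethanol 60 and negative (-0.09) with the adipocyte mean as a covariate. For *Acss1*, saline 36 held 389 CPM, against 156 to 277 in the other saline libraries.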

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

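The tests on glucocorticoid receptor targets and on adipocyte markers in this part were chosen after the values had been seen, while those on GC slope were written before their results. In 23 of 228 groups of 5 libraries that were examined (each named gene, library measure and list mean), 1 library stood far from the other 4. A library was taken as far when its Dixon ratio, the gap to its nearest neighbour over the range, exceeded 0.71. For independent and normally distributed values chance gives about 1 in 20, here 11.4. Gene CPM was not log-transformed and several items share genes, so the count of 23 groups does not measure an excess over chance.

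Saline 36 accounted for 6 of these. It held 239 CPM of *Cry2* (65.1 to 113 in the other saline libraries), 278 CPM of *Slc39a14* (28.2 to 93.9), 1262 CPM of *Bnip3* (731 to 859) and 130.5 CPM of *Maff* (39.5 to 58.7). Its mean of the cold-responsive list was high, at 6.345 (5.99 to 6.05), and that of the adipocyte list low, at 4.168 (4.74 to 4.90). The lower glucocorticoid receptor targets of the ethanol group rested in part on this mouse. The mean log2 CPM of the 20 genes was lower in ethanol by 0.53 ± 0.29 (SE over mice, exact permutation p = 0.1111). Without saline 36 the difference was -0.3069 ± 0.21 (exact permutation p = 0.214), and 19 genes of the list still had a negative log2 fold change. Saline 36 thus carried part of the difference, and whether the rest differs from 0 stays open. The median log2 fold change was -0.25 without saline 36 and -0.35 without saline 36 and ethanol 60. The GC trend of the libraries carried 0.0304 ± 0.0090 log2 (SE over mice) of the difference, opposite in sign to it, which argues against GC content as the source. An effect of ethanol stays open, as do handling and time of day, which were not tested.

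Ethanol 60 stood high in *Pck1*, at 143.7 CPM (29.0 to 52.5 in the other ethanol libraries), *Cyp2e1*, at 203.3 CPM (43.5 to 83.9), *Tie1*, at 58.18 CPM (49.5 to 51.2), and the fatty acid oxidation list mean, at 7.338 (7.13 to 7.18). Fat carried along in dissection could raise adipocyte markers in this library. The difference in the list mean was 0.65 ± 0.33 log2 with all libraries (SE over mice). Without ethanol 60 it was 0.3676 ± 0.20 log2 (SE over mice, exact permutation p = 0.0952). The median log2 fold change was 0.22 without saline 36 and ethanol 60. Ethanol 60 thus carried part of the difference, and whether the rest differs from 0 stays open. Over all 10 libraries the list mean differed between the groups at an exact permutation p of 0.03968 (adjusted p = 0.405 over 36 lists). An effect of ethanol on fat cells stays open, as does more fat in several of the ethanol samples, which was not tested.

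Ethanol 51 had 15.23 CPM of *Cry1* (9.34 to 10.7), 148.9 of *Mt1* (68.9 to 82.2) and 29.8 of *Atf3* (14.5 to 18.0). Ethanol 57 had 0.9048 CPM of *S100a8* (0.23 to 0.38), 1.877 of *S100a9* (0.47 to 0.74) and 0.7708 of *Retnlg* (0 to 0.16). Saline 39 had 3.213 CPM of *S100a8* (0.63 to 1.17), 5.839 of *S100a9* (1.23 to 2.24), a neutrophil list mean of 1.378 log2 CPM (-0.41 to 0.10) and 8.41 CPM of *Dbp* (6.07 to 6.57). Saline 34 had 30.51 CPM of *Fbxo21* (21.6 to 24.2) and 102.8 of *Rgcc* (132 to 143). Saline 38 had 80.38 CPM of *Cyp2e1* (29.5 to 42.4).

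Every ethanol library had a higher slope on GC content, relative to the mean of all libraries, than any saline library. The slope of centred log2 CPM on transcript GC content was -0.044 ± 0.038 per 10% GC in saline and 0.044 ± 0.015 in ethanol (SD, n = 5 each, exact permutation p = 0.00794, the smallest possible, not a planned test). After thinning to equal depth the difference was 0.9963 of its size, so fewer counts alone did not make it. Thinning removes counts without regard to GC content. It therefore could not test whether a step that made the ethanol libraries shallower also made the slope. Depth and slope both separated the groups completely and cannot be told apart here. The slope difference was at least 0.07472 in the low, middle and high expression classes, against 0.089 over all genes. A bias of library preparation or sequencing would give this. Any other difference tied to GC content could give it too, so it does not tell them apart. Added stromal and fat transcripts stay open as well: over 133 fibre, metabolic and ribosomal genes the slope difference was 0.728 of that over all genes, within its SE of 0.23 of the bound of 0.5. An effect of ethanol itself on GC-rich genes follows the same grouping and was not tested.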

How the results depend on the processing

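The fits with a list covariate, thinning, GC removal, 2 libraries left out and the other DESeq2 filter were chosen after seeing the data. The count of core clock genes and of glucocorticoid receptor targets past FDR 0.05 was 0 in all 23 alternatives. Genes at an unadjusted p under 0.05 numbered 918 to 1916 over the alternatives (1599 in the reported fit). Genes past the threshold numbered 54 with DESeq2 (38 higher, 16 lower) and 53 with its filtering at 0.05 (37 higher, 16 lower; *Lipe* was lost). Leaving out 1 library gave 0 to 1 (0 to 1 higher, 0 to 1 lower), with *Rgcc* past it without saline 34 and *Kcne4*, singled out after its value was seen, without ethanol 57. The other alternatives gave 0. The cause of the DESeq2 difference was not tested.

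Lists passing camera numbered 11, against 16 with no low-count filter, 14 with total count scaling, 12 with 1 surrogate variable and with GC removed, 7 to 13 with a library left out (7 without saline 39, 13 without ethanol 59), 11 with RLE and without robust estimation, 10 without saline 36 and ethanol 60, 9 at a mean of 5 CPM and thinned, 4 with the adipocyte mean as a covariate, 0 with an estimated correlation and 0 with fry's directional test. The last of these asks a different question from camera. Beside the gains given for the immediate early, macrophage, tendon and mTORC1 lists, the cytokine and polyamine lists passed with no low-count filter (adjusted p = 0.0222 and 0.0294), insulin and Schwann cell with 1 surrogate variable (0.0494 and 0.0295), NRF2 without ethanol 51 (0.03595) and cAMP without ethanol 59 (0.00792). The glucocorticoid receptor list had an adjusted p of 0.5214 with an estimated correlation and 0.3716 with fry, and 1.161e-08 to 0.001233 with a library left out. The ribosomal list turned to higher with 1 surrogate variable (adjusted p = 0.8838). The first principal component held 29.09% of the variance over all tested genes, and the total count difference was -10.59 M, or -8.692 M without the 10 most counted genes.

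Of 71 named genes, 65 kept their direction in each alternative. *Nr1d2* turned positive with GC removed (0.008043) and with the adipocyte covariate (0.004005). *Ciart* turned negative with limma-voom (-0.02861), GC removed (-0.01047) and thinning (-0.07957), and ran from -0.2429 to 0.2395 with a library left out. *Bhlhe40* was positive with total count scaling (0.03507), a mean of 5 CPM (0.008624), 1 surrogate variable (0.1311), without saline 36 and ethanol 60 (0.02831), thinned (0.03652) and with the adipocyte covariate (0.06695), and ran from -0.1194 to 0.07585. *Csnk1d* was positive without saline 36 and ethanol 60 (0.02074) and with the adipocyte covariate (0.03316), and ran from -0.09814 to 0.003509. *Timeless* was -0.007483 with GC removed and ran from -0.006749 to 0.07745. *Cyp2e1* was -0.09114 with the adipocyte covariate. The cause was not tested. The neutrophil genes lay near 1 CPM, and their median went from -1.18 to -0.61 after thinning to equal depth. These medians may rest on different members, since the low-count filter was applied again to the thinned counts.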

Other observations

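The test on clock phase below, and the counts over other splits for the genes past FDR 0.05, the core clock genes and the DESeq2 calls, were chosen after the values had been seen.

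Genes called by DESeq2 outside the lists, here singled out after their values were seen, included these. *Eln*, encoding elastin, had a log2 fold change of 0.50 (adjusted p = 0.0170), *Postn*, periostin, of 0.69 (adjusted p = 0.0347), *Col6a2* of 0.53 (adjusted p = 0.0331) and *Col8a1* of 0.46 (adjusted p = 0.0203). The Notch target gene *Hes1* stood at 1.07 (adjusted p = 0.00194) and *Rasd1*, a small G protein gene that dexamethasone induces, at 1.24 (adjusted p = 0.00581), opposite in sign to the 20 glucocorticoid receptor targets of the fixed list. The kinase gene *Map3k8* stood at -1.07 (adjusted p = 0.0119). None of these passed in edgeR.

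The 54 genes that DESeq2 called were compared with other splits of the 10 libraries into groups of 5. Of 100 splits, the real one included, 4 gave at least 54, and the highest other gave 427, a share just under 0.05. The count was picked after it was seen, from the 1 tool that called genes, and the 2 edgeR-based counts below do not exclude chance, so chance is not firmly excluded here. The split with 427, picked here as the largest of the 100, set saline 32, 36, 38 and 39 with ethanol 51 against saline 34 with the other ethanol libraries. It divides the libraries by their sign on the first principal component. Ethanol 51 and the saline libraries set with it were negative, from -20.5 (saline 36) to -1.36 (ethanol 51). Saline 34 and the other ethanol libraries were positive, from 2.83 (ethanol 62) to 12.4 (ethanol 57). The largest count thus followed the main axis of variation between mice, on which the saline and ethanol ranges overlap. What underlies that axis was not tested. For 1599 genes at an unadjusted p under 0.05 in edgeR, 6 of 100 splits gave as many, up to 2343 in another split, and chance is not excluded. For the 11 lists called by camera 44 of 100 splits gave as many, up to 20, so that number is no more than splits of these libraries give. With 0 genes past FDR 0.05 in edgeR, 100 of 100 splits gave at least as many (up to 12), and with 0 core clock genes 100 of 100 (up to 0), which a count of 0 fixes in advance, so these say nothing on chance.

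Clock state and glucocorticoid targets varied together from mouse to mouse. A phase index was formed as the mean log2 CPM of *Arntl*, *Clock* and *Npas2* minus that of *Dbp*, *Per3*, *Ciart*, *Nr1d1*, *Nr1d2* and *Tef* (the last outside the rule for named genes), genes that peak at roughly opposite times of day. With group means removed it correlated over the 10 libraries with the mean of the glucocorticoid receptor targets (Pearson r = 0.73, exact permutation p within groups 0.0241, Spearman rho = 0.71, p = 0.0319). Without saline 39 and ethanol 57, the libraries farthest out on the index once group means were removed, r was 0.79. This was the 1 such relation computed. The index was 0.12 ± 0.46 in saline and -0.31 ± 0.64 in ethanol (SD, n = 5 each, exact permutation p = 0.246). A hypothesis is that the mice differ along 1 axis of time of day or stress hormone exposure, with ethanol 57 (-1.11) and ethanol 59 (-0.876) at one end and saline 36 (0.666) at the other. The same libraries lay at the ends of the first principal component, at 12.4, 10.3 and -20.5. They also held the lowest and highest means of the autophagy list (6.31, 6.38 and 6.88 log2 CPM). The same held for the ubiquitin ligase and p53 lists. The relation is therefore not particular to clock and glucocorticoid genes. Collection times per mouse, which would test the hypothesis, were not used here.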
